A study of Mus musculus with 60 samples.

How the data were processed

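Gene expression was measured by RNA-seq in fetal liver, placenta and brain of mice, in 60 libraries of 20 groups. RNA was extracted with Qiagen RNeasy kits and sequenced on an Illumina NovaSeq instrument per the labels' protocols. Per the submitters' processing notes, reads were demultiplexed with DRAGEN, inspected with FastQC, trimmed with cutadapt, aligned to mm10 with HISAT2, counted per gene with featureCounts and tested with limma, with no versions given. The authors deposited a table of raw counts for 27179 genes with no normalization per the file headers. The authors also deposited 10 tables of limma-voom results, which give log2 fold changes and mean log2 expression, p-values and adjusted p-values per the file headers, with no statement of the filter or the design. A further deposited table holds codes of RNA extraction and RNA clean-up batches, 1 per library.

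Counts were tested with edgeR 4.0.16 (R 4.3.3). Each tissue and treatment was fitted with its control in both sexes, 12 libraries in 4 groups, and the compounds were compared in fits of the 24 libraries of a tissue. Genes were kept by filterByExpr by group (min.count 10, min.total.count 15), library sizes were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood test was robust. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast with a threshold of 0.05. There were 24 contrasts: 10 of treatment within a sex, 5 of the difference between the sexes (male effect minus female effect), 5 of their average and 4 of keto minus βOHB. The fitted model pools the spread over groups, and a test on 3 libraries against 3 alone could not reach an exact two-sided p below 0.1.

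Before the data were examined, 41 gene lists (pathways, cell-type markers and sex-linked genes, 1106 entries of which 16 matched no gene), the contrasts, the tests and the rule for named genes were fixed. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists of a contrast, and again with an estimated correlation. Genes were named by this rule: among genes passing in a contrast within a sex, with a mean of at least 1 CPM and all 3 treated libraries on one side of all 3 controls, the 8 largest increases and the 8 largest decreases; up to 10 list members by p; the 5 smallest p-values where fewer passed; 8 genes, or 3 where none passed, for each difference, average and compound contrast; and Hmgcs2, Bdh1, Oxct1 and Slc16a1. Predicted genes and clones were left out of the naming. The 3 examples given per list, the interferon, Hox and placental marker levels and the genes shown for both sexes were chosen after their values were seen.

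Symbols of 25275 genes and all positions were taken from a RefSeq table of GRCm38.p6, the assembly that mm10 denotes, and 156 symbols from the deposited tables; 1748 genes had none. Total counts per library, with a median of 20760789.5, set the precision, and the floors used for genes at 0 cover counting error only. List medians were recomputed with members at a floor of 3 counts over the group, which moved none by more than 0.045.

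Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors (RLE) in place of TMM, no low-count filter, the replicate number as a block, only the 6 libraries compared or only the 12 of that sex, each library left out in turn, and for correlations only genes with a mean of at least 10 CPM. Added after the results were seen were a correction for transcript length and GC content (splines with 4 degrees of freedom), fits of all 60 libraries with edgeR or limma-voom, limma-voom with the batch codes as terms using approximate or exact standard errors, the RNA clean-up batch in brain, the list tests under the block, and the list tests and list medians with libraries left out. Because the titles number replicates 1 to 3 without saying what a number marks, a replicate number was taken as a pair only where deviations of the treated and control library with the same number correlated above r = 0.1 in each pair. This held in female keto placentas (r = 0.24, 0.24 and 0.26), so the blocked values stand beside those results where the block changed a call.

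The tests were tested on simulated data with 200 changed genes in the libraries of female keto livers (13702 genes). Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 50.7%, 79.1% and 89.4% and called 6 unchanged genes. DESeq2 recovered 52.2%, 82.1% and 95.5% with 21 unchanged genes called, and limma-voom 49.3%, 76.1% and 89.4% with 6. Libraries were checked for duplicates over 60 pairs, none of which were copies (lowest chi-square per degree of freedom 12.6). No library was left out of the tests; the library whose sex label disagreed with its Y-linked genes was kept under its label and left out in turn. Correlations and splits were computed in R, and file preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Permutation tests of single genes or regions across tissues drew 10000 reassignments of fetuses, the count of genes with r above 0.8 drew 1000, tests of correlated values drew 1e+05, and the correlation of βOHB with keto effects was set against 200 splits of the libraries.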

Results

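RNA was sequenced from fetal mouse tissues after the embryos had been cultured, before implantation, with ketone bodies, the small acids that the liver makes from fat during fasting. Embryos were cultured with 2 mM β-hydroxybutyrate (βOHB), with 2 mM βOHB plus 0.8 mM acetoacetate (AcAc; this mixture is called keto here) or without either, and were then transferred to recipient females. Tissues were taken at E14.5 per the labels, although the tissue label itself gives day 13.5. Each treatment had its own control, control1 for βOHB and control2 for keto, so that no control library served both. Liver and placenta were sequenced in all 4 conditions and brain in keto and control2, from females and males, with 3 libraries in each of 20 groups. Libraries of different tissues with the same group and replicate number came from the same fetus per the library codes. Total counts per library were 15181363 to 23278522 in liver, 15333522 to 26902717 in placenta and 18317773 to 27389946 in brain, over 27179 genes. Levels are given as CPM, the counts of a gene scaled to the effective library size (mean ± SD, n = 3 per group), and differences as log2 fold changes (treated over control) with their standard error. The sex-linked genes used to check the labels were scaled to total counts instead, also where Xist is compared with decidual markers.

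The sex labels were compared with Xist, which is transcribed from the inactive X chromosome of females, and with 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty). In the 30 libraries labelled female, Xist ranged from 17.6 to 315.03 CPM and the Y-linked genes summed to at most 0.05 CPM. In 29 of the libraries labelled male, Xist was at most 3.09 CPM and the Y-linked sum ranged from 72.34 to 182.05 CPM. The library labelled bOHB_placenta_M replicate 2 had 27.52 CPM of Xist and 0.08 CPM of Y-linked genes, against its label, so every direction in the male βOHB placenta rests partly on it.

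**Figure D1:**
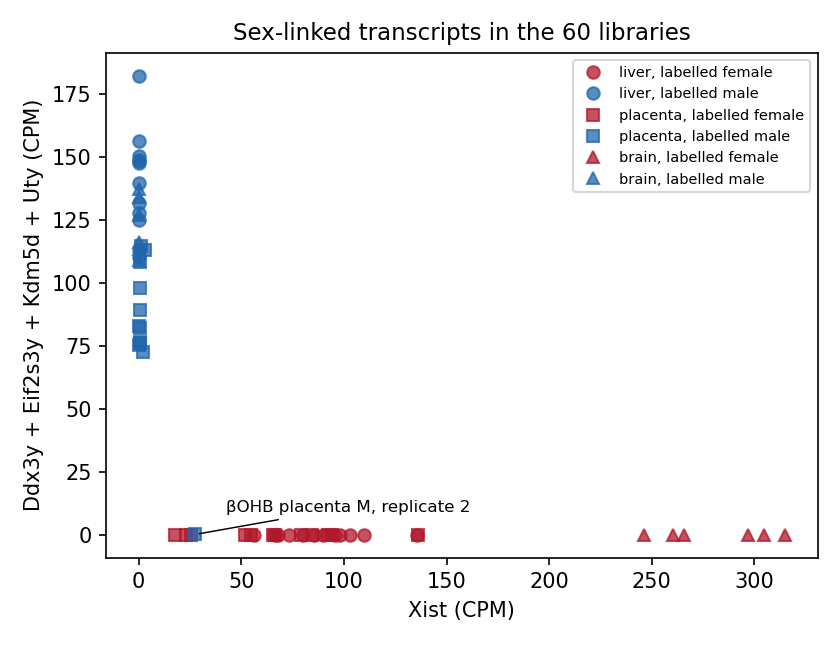
Xist (x axis, CPM) against the sum of Ddx3y, Eif2s3y, Kdm5d and Uty (y axis, CPM), 1 point per library. The library labelled bOHB_placenta_M replicate 2, at 27.52 and 0.08 CPM, lies among the libraries labelled female.

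Whether culture with keto altered gene expression in the fetal liver was asked in each sex. In female livers, 798 genes were higher and 444 lower than in control2 livers (edgeR, Benjamini-Hochberg adjusted p < 0.05, 13720 genes tested), and DESeq2 called 992 higher and 858 lower. Single genes of mRNA decay, cell-cycle entry and sterol synthesis were among those that rose, but the cell cycle and cholesterol synthesis lists did not pass. The ribosomal protein and oxidative phosphorylation lists fell by camera at the preset correlation (adjusted p = 0.993 with an estimated correlation). Cnot6l, a deadenylase that shortens mRNA tails, rose from 5.93 ± 1.25 to 18.6 ± 1.58 CPM (log2 1.64 ± 0.15 SE, adjusted p = 0.000361; chr5 96070333 to 96164198, GRCm38). Mob1a, a coactivator of the Hippo pathway kinases, rose from 9.8 ± 2.09 to 38.5 ± 6.93 CPM (chr6 83326034 to 83342812).

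The cyclin gene Ccne2 rose in keto females from 53.9 ± 8.96 to 121.4 ± 9.89 CPM (adjusted p = 0.000454; chr4 11190433 to 11204779). Foxo3, a transcription factor of stress resistance, rose from 18.3 ± 0.798 to 41.8 ± 1.96 CPM (log2 1.19 ± 0.13, adjusted p = 0.000526; chr10 42181845 to 42276695). Among the 8 largest increases were Mia2 (log2 2.84 ± 0.43; chr12 59095582 to 59190220), Megf9 (2.38 ± 0.31; chr4 70431927 to 70534928), the nuclear receptor corepressor Nrip1 (2.36 ± 0.25; chr16 76287403 to 76373827) and the Hedgehog receptor Ptch1 (2.27 ± 0.33; chr13 63508328 to 63573460). Zbed6, Slc10a5, Cpeb4 and Rassf8 made up the rest of the 8, at log2 2.49, 2.42, 2.37 and 2.25. Without control2_liver_F replicate 1, Zbed6, Slc10a5 and Cpeb4 no longer passed (adjusted p = 0.134, 0.0631 and 0.0806), nor did they or Rassf8 without control2_liver_F replicate 2 (0.123, 0.0673, 0.073 and 0.0519). Zbed6 and Cpeb4 also missed without keto_liver_F replicate 1 (0.128 and 0.0627), and Zbed6 without keto_liver_F replicate 2 (0.0595). In sterol synthesis, Idi1 rose from 15.5 ± 6.7 to 38.7 ± 2.71 CPM and Dhcr24 by log2 0.66 ± 0.12. The apolipoprotein gene Apom rose by log2 1.06 ± 0.17.

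The largest decreases in keto females included Pop4, a subunit of the ribonuclease P and MRP complexes, which fell from 30.8 ± 10.8 to 7.87 ± 0.592 CPM (log2 -1.96 ± 0.33, adjusted p = 0.00857; chr7 38262812 to 38271393). Atp5e, a subunit of ATP synthase, fell from 232.1 ± 29.1 to 133.7 ± 13.5 CPM (log2 -0.80 ± 0.11). Abcc6 (-1.86), Rn18s (-1.68), Lars2 (-1.52), Rn7sk (-1.42), Particl (-1.13), the mitochondrially encoded ND3 (-0.95) and Rpl26 (-0.89) also passed. Reads of Rn18s, Lars2 and the ribosomal protein genes can be shared with near-identical copies, so their values are uncertain. In a comparison added after the results were seen, Rpl26 in liver followed Rpl26 in placenta of the same fetus (r = 0.948), as Pop4 did (r = 0.963). An effect of keto on either gene cannot be separated from the draw of fetuses. After correction for transcript length and GC content, Abcc6, Rn18s, Lars2, Rn7sk and Rpl26 no longer passed (adjusted p = 0.0561, 0.0556, 0.0512, 0.0663 and 0.0999). Without keto_liver_F replicate 1, adjusted p was 0.159 for Abcc6, 0.176 for Rn18s, 0.167 for Lars2, 0.11 for Rn7sk, 0.112 for Particl and 0.053 for ND3, and for Rpl26 it was 0.124 without control2_liver_F replicate 1. Each of the other libraries compared also ended the call of at least 1 of these genes when left out, whereas Pop4 and Atp5e passed each time.

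All 74 ribosomal protein genes were lower in keto females (median log2 -0.46, camera adjusted p = 1.15e-30; 38 genes passed on their own and 58 adjusted over the list alone), with Rpl36 at -0.67 and Rps25 at -0.60. Of 43 nuclear genes of oxidative phosphorylation, 38 were lower (median -0.31, adjusted p = 5.98e-11; 13 lower and 1 higher on their own, 21 and 1 adjusted over the list alone), among them Uqcrb at -0.53 and Atp5o at -0.43. Uqcrb had adjusted p = 0.052 without control2_liver_F replicate 1, and Atp5o 0.0631 without control2_liver_F replicate 1 or 2. The 12 measured mitochondrially encoded genes were also lower (median -0.55, adjusted p = 4e-05; 1 on its own and 6 adjusted over the list alone). In the list of X and Y genes the X-linked Eif2s3x, Ddx3x and Kdm6a rose by log2 0.70, 0.58 and 0.73 (camera adjusted p = 0.0023 for the list, 4 genes adjusted over the list alone). Of the 9 members, 4 had at most 3 counts over a group, so the list value rests partly on genes that were barely counted. The list median of 0.247 was 0.098 without control2_liver_F replicate 2 and 0.034 without keto_liver_F replicate 1. Erythroid markers were higher in 21 of 29 (camera adjusted p = 0.0375) and genes of DNA and histone methylation in 21 of 24 (camera adjusted p = 0.0481). Single libraries left out ended both calls, with adjusted p up to 0.237 without keto_liver_F replicate 2 for the former and 0.241 without keto_liver_F replicate 1 for the latter, whose median went from 0.147 to 0.080. Every list named here lost its call with an estimated correlation (adjusted p = 0.993 with an estimated correlation). Fold changes over all genes also followed transcript length in keto females (Spearman's rho 0.299), a further limit on these lists.

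**Figure D2:**
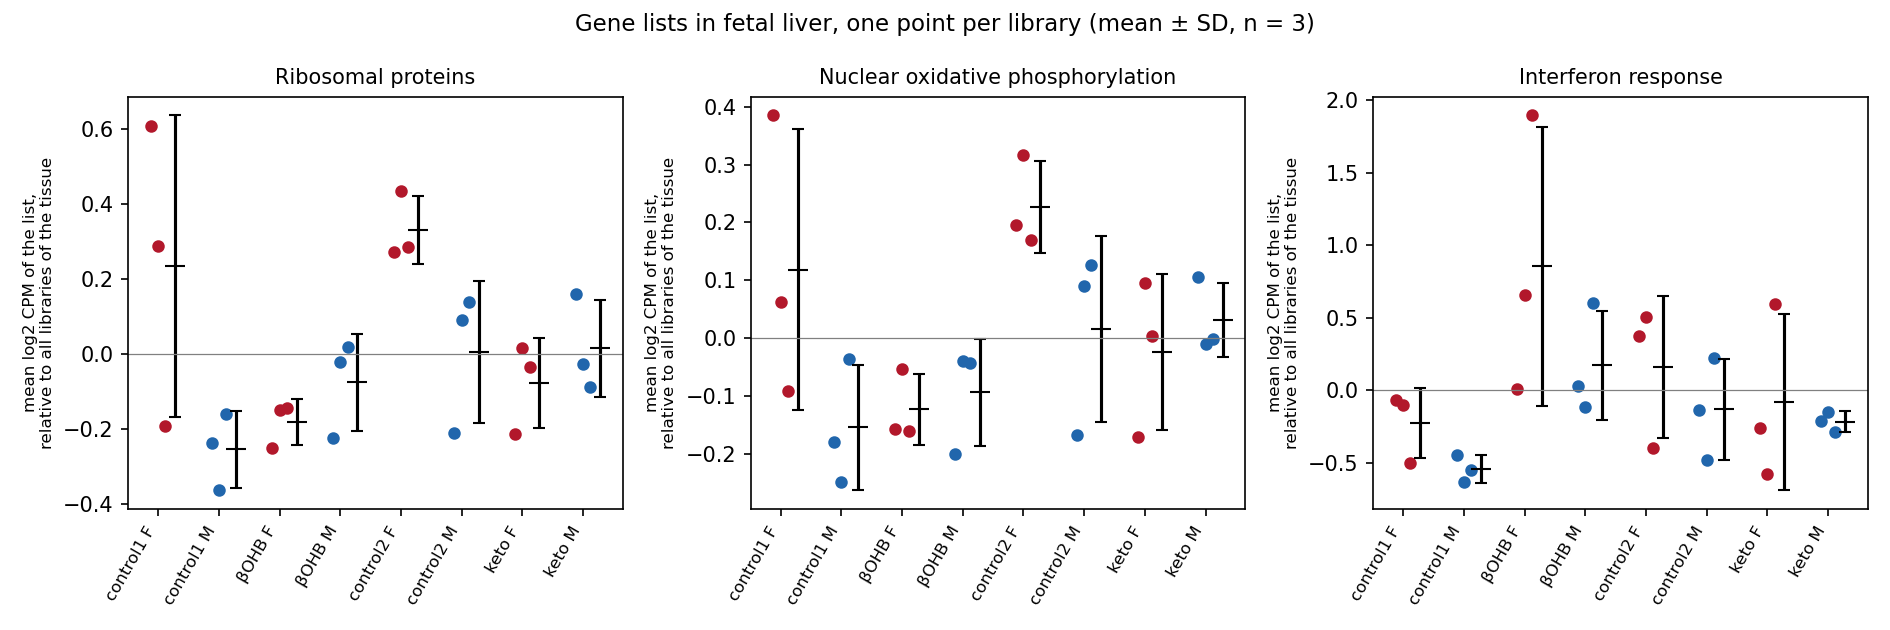
Mean log2 CPM of the ribosomal protein, oxidative phosphorylation and interferon response lists relative to all liver libraries (y axis) by group (x axis), 1 point per library with the mean ± SD (n = 3). In the ribosomal protein list the control2 females score 0.273, 0.436 and 0.285.

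The control2 females and control1_liver_F replicates 1 and 2 stood apart from the other livers in these genes. For 1231 of the 1242 genes called in keto females, control2 females were the outermost of the 4 groups of the comparison, for 753 keto females were, and for 1100 control2 females were the outermost of all 8 liver groups. Because the genes were called on a difference between these 2 groups, an end position of either is partly built in. Counted in the direction of each call, control2 males lay a median log2 0.41 beyond control2 females and keto females 0.49 beyond them. Scores of the called genes were -0.430, -0.436 and -0.289 in control2 females and -0.461, -0.320 and 0.138 in control1 females, and they lay between -0.056 and 0.232 in the other livers. The count of calls fell to 213 without control2_liver_F replicate 1, to 378 without control2_liver_F replicate 2 and to 416 without keto_liver_F replicate 1.

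In male livers after keto, edgeR called 0 genes, with 605 at an unadjusted p < 0.05, DESeq2 called 4 and limma-voom 0. Agxt, a liver enzyme of glyoxylate breakdown, measured 8.95 ± 0.597 CPM against 37.9 ± 7.02 in controls (log2 -2.08, adjusted p = 0.996), and Hsd17b14 and Mab21l4 gave log2 1.48 and -3.49 (adjusted p = 0.408). All 15 megakaryocyte markers were higher (median 0.29, camera adjusted p = 4.9e-10, 0.983 with an estimated correlation), with Gp6 at 0.91, Gp1ba at 0.62 and Itgb3 at 0.38, and a median of 0.191 without control2_liver_M replicate 1. Mitochondrially encoded genes were lower in 11 of 12 (median -0.28, adjusted p = 0.000604; 0.0888 without keto_liver_M replicate 3, 0.983 with an estimated correlation), with a median of -0.127 without that library, -0.148 without control2_liver_M replicate 3 and -0.438 without keto_liver_M replicate 1.

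The effect of keto in the liver differed between the sexes for 1 gene, Cnot6l (male effect minus female effect -1.55 ± 0.21, adjusted p = 0.0326), which measured 17.5 ± 2.52 CPM in control2 males and 18.7 ± 0.694 in keto males. DESeq2 called 253 genes, limma-voom 0, and 1911 had an unadjusted p < 0.05. Leaving out control2_liver_F replicate 1, control2_liver_M replicate 1 or 3, keto_liver_F replicate 2 or 3 or keto_liver_M replicate 3 left 0 genes, and leaving out control2_liver_F replicate 3 gave 174. Averaged over both sexes, 211 genes were higher and 35 lower (DESeq2, 900 genes; limma-voom, 196), and 238 of these 246 were also called in females. Of the 246 average calls, 238 had the same sign in both sexes. The 1242 genes called in females had a median of 0.488 in the direction of the call in females and 0.049 in males. In males, 69.3% of the 1242 had the same sign, and 969 passed at 0.05, unadjusted, for the difference between the sexes. Because these genes were called in females, a larger effect there is partly built in. These values therefore do not show how much of the averages came from females. Foxo3 averaged log2 0.74 ± 0.09 (adjusted p = 0.00393), with 1.19 in females and 0.30 in males. Diaph1 (chr18 37843601 to 37935622) averaged 0.51, with 0.80 and 0.23, and the mitotic kinase gene Nek7 0.46 ± 0.07, with 0.73 and 0.19. None of the 3 male effects passed (adjusted p = 0.996). The averaged count was 1123 without control2_liver_M replicate 1, and it lay between 12 and 66 without control2_liver_F replicate 1 or 2, control2_liver_M replicate 2 or 3, keto_liver_F replicate 1 or 2, or keto_liver_M replicate 2 or 3.

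Culture with βOHB alone was compared with control1 in the liver. Interferon response genes were higher in βOHB livers of both sexes, and the ribosomal protein and mitochondrially encoded lists moved in opposite directions in females and males (camera adjusted p = 8.82e-28 and 7.73e-15 for the difference between the sexes, 0.684 with an estimated correlation). None of these lists passed within a sex with an estimated correlation (adjusted p = 0.603 to 0.766). Fold changes over all genes also followed transcript length in opposite directions (Spearman's rho 0.156 in females and -0.148 in males). This trend is a further limit on the opposite directions of the lists. No gene passed in females (edgeR; 1614 at an unadjusted p < 0.05; DESeq2 16, limma-voom 0) or in males (175; DESeq2 1, limma-voom 0), among 14148 tested. All 30 interferon response genes were higher in females (median 1.36, camera adjusted p = 8.15e-19; 22 genes adjusted over the list alone, 0.766 with an estimated correlation) and in males (median 0.72, adjusted p = 9.23e-17; 1 gene adjusted over the list alone, 0.603 with an estimated correlation). The medians were 0.493 without bOHB_liver_F replicate 3 and 0.391 without bOHB_liver_M replicate 3. The antiviral gene Rsad2 ranged from 24.7 to 35.8 CPM in βOHB females against 9.68 to 16.3 in control1 females, and from 36.4 to 50.7 CPM in βOHB males against 5.23 to 18.8 in control1 males. In the untreated control2 males it ranged from 24.1 to 43.1 CPM, which overlaps the βOHB males.

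Among single genes of the βOHB female liver, the RNA editing enzyme gene Adar measured 56.5 ± 21.3 CPM against 25.9 ± 1.9 (log2 1.13 ± 0.21, adjusted p = 0.435), and the signalling genes Stat1, Irf9 and Irf7 gave 1.51, 1.30 and 2.49. The increase differed between libraries: Irf7 measured 7.66, 15.8 and 60.8 CPM in the βOHB females and 3.79 to 5.53 in their controls. Isg15, a ubiquitin-like antiviral protein, measured 4.56, 11.9 and 84.4 CPM against 1.61 to 5.25, so that the groups overlapped. The ribosomal protein list was lower in 73 of 74 genes (median -0.49, adjusted p = 2.29e-27; 39 genes adjusted over the list alone), with Rpl37a at -0.80. All 13 mitochondrially encoded genes were lower (median -1.30, adjusted p = 6.89e-14; 10 adjusted over the list alone), with ND5 at -1.29 and ND2 at -1.49. Of 43 nuclear oxidative phosphorylation genes, 34 were lower (median -0.31, adjusted p = 2.72e-08). These 3 lists had adjusted p = 0.766 with an estimated correlation. They moved with libraries that stood apart: control1 females scored 0.608, 0.288 and -0.192 for the ribosomal proteins, and the mitochondrially encoded list scored 1.664 in control1_liver_F replicate 1. Without that library the medians were -0.243 for the ribosomal proteins, -0.650 for the mitochondrially encoded genes and -0.103 for nuclear oxidative phosphorylation. Without control1_liver_F replicate 3, 1480 genes passed in females.

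Male βOHB livers had higher levels of all 15 megakaryocyte markers (median 0.32, camera adjusted p = 2.36e-13, 0.603 with an estimated correlation), with Gp9 at 0.39, Gp1bb at 0.58 and Gp5 at 0.46. Ribosomal proteins were higher in 70 of 74 genes (median 0.12, adjusted p = 2.49e-07, 0.686 with an estimated correlation) and mitochondrially encoded genes in 13 of 13 (median 0.41, adjusted p = 0.000101; 0.0629 without bOHB_liver_M replicate 2, 0.603 with an estimated correlation). Genes of fatty acid and triglyceride synthesis were lower in 17 of 19, with Scd1 at -0.32 (adjusted p = 0.000422; 0.0882 without bOHB_liver_M replicate 3, 0.603 with an estimated correlation), while in females 17 of 19 were higher (adjusted p = 0.00665; 0.067 without control1_liver_F replicate 2, 0.766 with an estimated correlation). Medians of this list went from -0.176 in males to -0.284, -0.094 and -0.103 without bOHB_liver_M replicate 1, bOHB_liver_M replicate 3 and control1_liver_M replicate 2, and from 0.155 in females to 0.314 and 0.312 without bOHB_liver_F replicate 3 and control1_liver_F replicate 3. In males the ribosomal protein median was 0.069 and 0.064 without bOHB_liver_M replicate 3 and control1_liver_M replicate 2, and 0.192 and 0.205 without bOHB_liver_M replicate 1 and control1_liver_M replicate 3, and the mitochondrially encoded median was 0.208 without bOHB_liver_M replicate 2. No gene passed for the difference between the sexes (1114 at an unadjusted p < 0.05; DESeq2 0, limma-voom 0) or for their average (435; DESeq2 3, limma-voom 0), where Rsad2 gave log2 1.501 (adjusted p = 0.99). Leaving out control1_liver_F replicate 3 gave 441 genes for the difference and 13 for the average.

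In the placenta, βOHB was compared with control1, including markers of fetal and maternal tissue. Marker levels in whole placenta samples do not separate a response of a tissue from its share in the sample. Female βOHB placentas had lower levels of cholesterol synthesis genes, of decidual, myeloid and uterine natural killer cell markers, and of hepatocyte and yolk sac markers, by camera at the preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.186 to 0.516). No gene passed in females (edgeR; 1020 at an unadjusted p < 0.05; limma-voom 0), where DESeq2 called 65, all lower, among 14682 tested; without control1_placenta_F replicate 3, edgeR called 64. Abcc5, an exporter of cyclic nucleotides, measured 16.3 ± 2.91 CPM against 35.8 ± 8.48 (log2 -1.13 ± 0.19, adjusted p = 0.556), and the steroid reductase gene Srd5a1 measured 14.3 ± 1.3 against 39.0 ± 3.76 (-1.45). All 25 cholesterol genes were lower in females (median -0.47, camera adjusted p = 1.85e-09; 3 adjusted over the list alone, 0.402 with an estimated correlation), with Hmgcs1 at -0.87, Idi1 at -1.46 and Fdps at -0.83. The cholesterol list scored 0.913 and 0.845 in control1_placenta_F replicates 1 and 2, which were also the highest of these 6 libraries for yolk sac markers (3.295 and 2.672), and -0.187 in the third control against -0.179, 0.008 and 0.144 in the βOHB females. Without control1_placenta_F replicate 1 its median was -0.310.

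Decidua and uterus markers were lower in 20 of 23 in βOHB females (median -1.04, adjusted p = 1.93e-12; 3 adjusted over the list alone, 0.211 with an estimated correlation), with Cyp11a1 at 44.3 ± 18.9 CPM against 99.6 ± 19.1 and Esr1 at -1.60. Myeloid markers were lower in 18 of 22 (median -1.09, adjusted p = 3e-12; 10 adjusted over the list alone, 0.186 with an estimated correlation), with Fcer1g at -1.35 and Itgam at -2.20, and their median was -0.633 without control1_placenta_F replicate 3. Uterine natural killer cell markers were lower in 10 of 11 (median -1.73, adjusted p = 3.05e-12, 0.301 with an estimated correlation), with perforin (Prf1) at 7.48 ± 5.17 CPM against 30.7 ± 10.4. In bOHB_placenta_F replicate 3 the natural killer list scored -2.822 (other βOHB females -0.127 and -0.493, controls 0.313 to 1.158) and the decidual list -1.237 (0.271 and -0.203, controls 0.664 to 0.914), and without it the medians were -1.213 and -0.909. All 29 hepatocyte markers (median -2.83, adjusted p = 2.81e-16) and all 19 yolk sac markers (median -2.51, adjusted p = 1.49e-10) were lower, with Apoe at -2.55, Hnf4a at -2.75 and Trf at -2.76 (adjusted p = 0.516 with an estimated correlation for both lists). Levels of these markers varied widely between placentas: Afp ranged from 1.92 CPM in control2_placenta_M replicate 1 to 20682.9 CPM in control1_placenta_F replicate 1, with a median of 1315.6. Cell cycle genes were higher in 34 of 35 (median 0.40, adjusted p = 0.00506, 0.836 with an estimated correlation), but this rested on bOHB_placenta_F replicate 3, which scored 1.488 against 0.116 and -0.232 in the other βOHB females and 0.259 to 0.318 in the controls. Without it the list was lower in 33 of 35 (median -0.306, adjusted p = 9.52e-09), and without control1_placenta_F replicate 3 adjusted p was 0.057. Without bOHB_placenta_F replicate 2 the median was 0.735.

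In the male βOHB placenta, no gene passed (edgeR; 135 at an unadjusted p < 0.05; DESeq2 0, limma-voom 0), nor without the library labelled bOHB_placenta_M replicate 2 (284 at an unadjusted p < 0.05). Hepatocyte markers were higher in 28 of 29 (median 1.60, camera adjusted p = 3.75e-11) and yolk sac markers in 19 of 19 (median 1.35, adjusted p = 2.16e-09), with albumin (Alb) at 69.6 ± 62.6 CPM against 10.96 ± 8.89 (adjusted p = 0.841 with an estimated correlation for both). Medians of these lists were 0.961 and 0.795 without bOHB_placenta_M replicate 1, and 1.042 for hepatocyte markers without control1_placenta_M replicate 1. Cell cycle genes were higher in 34 of 35 (median 0.30, adjusted p = 2.14e-06, 0.881 with an estimated correlation), with Mki67 at 0.56 and Mcm6 at 0.30. Interferon response genes were higher in 25 of 30 (adjusted p = 9.27e-06) and decidual markers lower in 17 of 23 (adjusted p = 8.23e-06), and without the library labelled bOHB_placenta_M replicate 2 these gave adjusted p = 0.37 and 0.66 (adjusted p = 0.841 with an estimated correlation for both) and medians of 0.033 and -0.055, from 0.162 and -0.273. The interferon median was 0.253 without bOHB_placenta_M replicate 3, and the decidual one -0.523 and -0.443 without bOHB_placenta_M replicates 1 and 3. No gene passed for the difference between the sexes (644 at an unadjusted p < 0.05; DESeq2 0, limma-voom 0) or their average (561; DESeq2 7, limma-voom 0).

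**Figure D3:**
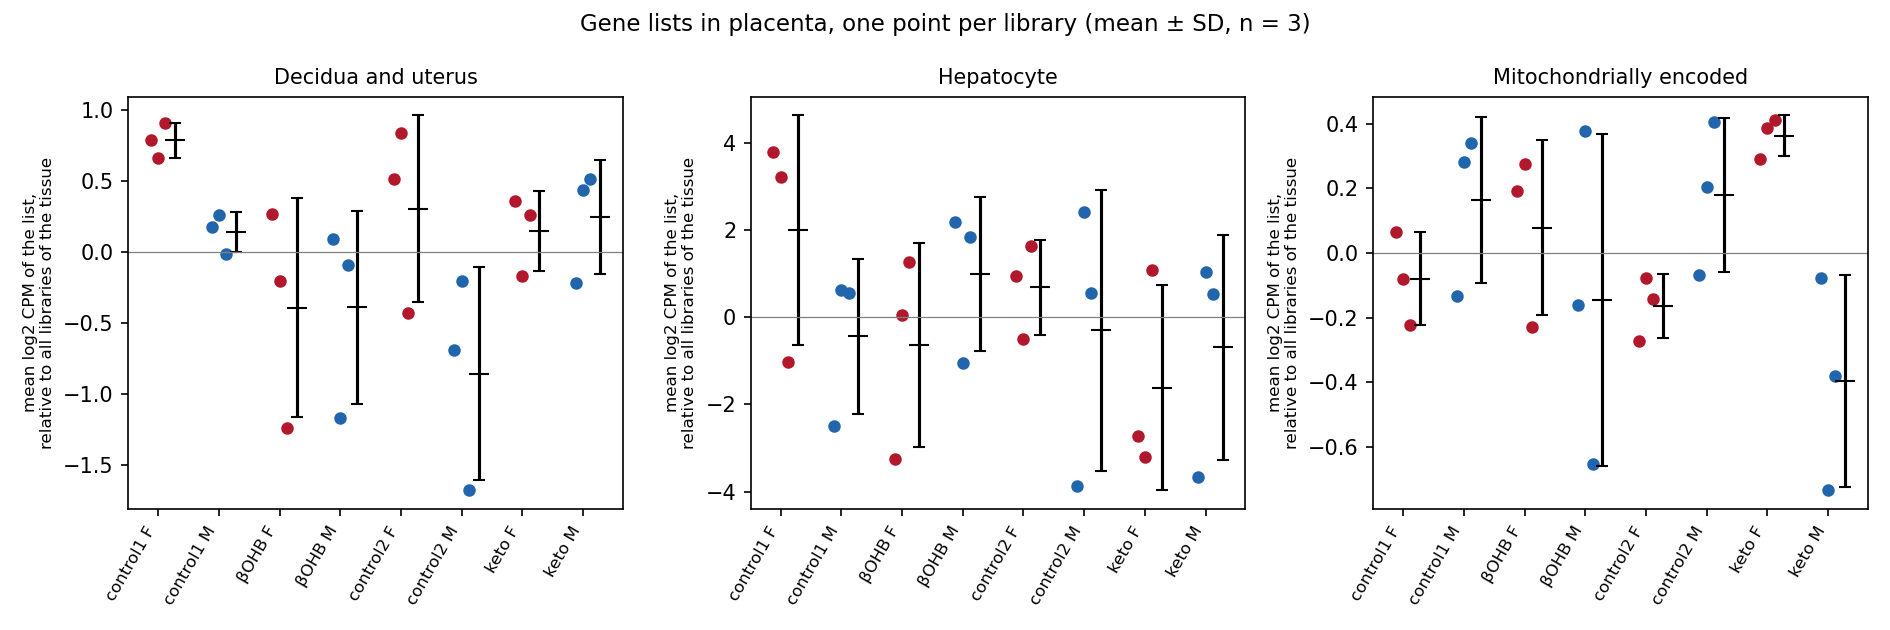
Mean log2 CPM of the decidua and uterus, hepatocyte and mitochondrially encoded lists relative to all placenta libraries (y axis) by group (x axis), 1 point per library with the mean ± SD (n = 3). In the male keto comparison the decidua and uterus list had a median log2 fold change of 1.08.

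Culture with keto was then compared with control2 in the placenta, with the same limit on marker levels. Female keto placentas had higher ribosomal protein, mitochondrially encoded and trophoblast giant cell genes and lower labyrinth markers, while male keto placentas had lower oxidative phosphorylation genes and higher endothelial, decidual and myeloid markers, by camera at the preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.159 to 0.517 in females and 0.362 to 0.401 in males). Transcript length was also followed by the fold changes in opposite directions (Spearman's rho -0.094 in females and 0.217 in males), a further limit on differences between the sexes. In females, 0 genes passed (edgeR; 558 at an unadjusted p < 0.05; DESeq2 4, limma-voom 0), and 1 passed with the replicate number as a block, among 14427 tested. The DNA polymerase gene Pold1 measured 5.64 ± 1.38 CPM against 13.4 ± 2.57 (log2 -1.25 ± 0.21, adjusted p = 0.932). Ribosomal proteins were higher in 72 of 74 (median 0.27, camera adjusted p = 1.67e-31, 0.517 with an estimated correlation), with Rps24 at 721.8 ± 56.3 CPM against 528.9 ± 12.03 and a median of 0.176 without keto_placenta_F replicate 1. All 12 mitochondrially encoded genes were higher (median 0.57, adjusted p = 3.52e-14; 8 adjusted over the list alone, 0.159 with an estimated correlation), with COX1 at 0.58 and ND5 at 0.69.

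Trophoblast giant cell markers were higher in 22 of 26 in keto females (median 0.25, adjusted p = 1.44e-07, 0.305 with an estimated correlation), with the prolactin-family genes Prl7a1 at 361.4 ± 59.8 CPM against 160.5 ± 73.1, Prl2c2 at 0.71 and Prl3d1 at 1.03, and a median of 0.456 without control2_placenta_F replicate 2. Junctional zone markers were higher in 28 of 33 (median 0.26, adjusted p = 1.65e-05; 0.127 without keto_placenta_F replicate 2, 0.517 with an estimated correlation), with a median of 0.144 without that library, 0.143 without control2_placenta_F replicate 1 and 0.437 without keto_placenta_F replicate 1. Labyrinth syncytiotrophoblast markers were lower in 26 of 30 (median -0.25, adjusted p = 7.27e-08, 0.414 with an estimated correlation), with Cebpa at -0.57 and the glucose transporter gene Slc2a3 at -0.38, and a median of -0.123 without control2_placenta_F replicate 1 and -0.146 without keto_placenta_F replicate 2. Hepatocyte markers were lower in 27 of 28 (median -1.16, adjusted p = 7.27e-08) and yolk sac markers in 19 of 19 (median -1.01, adjusted p = 1.05e-07, 0.517 with an estimated correlation for both). Without keto_placenta_F replicate 3 these medians were -4.965 and -3.496, without replicate 1 of that group -0.693 and -0.667, without replicate 2 -0.684 and -0.652, and without control2_placenta_F replicate 3 -0.454 and -0.537. Genes of fatty acid oxidation were lower in 19 of 23 (adjusted p = 0.0218, 0.517 with an estimated correlation) and genes of ketone body metabolism and transport in 10 of 12 (adjusted p = 0.0452, 0.517 with an estimated correlation). With the replicate block both had adjusted p = 0.0582, and without keto_placenta_F replicate 2 both had 0.427 and medians of -0.026 and -0.071, from -0.086 and -0.129. The medians were -0.171 and -0.383 without keto_placenta_F replicate 1, the first was -0.039 without control2_placenta_F replicate 1, and the second was -0.242 without control2_placenta_F replicate 3. Choroid plexus markers, lower in 11 of 15 (adjusted p = 0.122, 0.517 with an estimated correlation), passed with the block (0.00448).

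In male keto placentas, 0 genes passed (edgeR; 1995 at an unadjusted p < 0.05; limma-voom 0), while DESeq2 called 139 higher and 97 lower, and edgeR called 1 without keto_placenta_M replicate 2. Plxnd1, a semaphorin receptor of vessels, measured 83.8 ± 5.88 CPM against 51.8 ± 4.57 (log2 0.69 ± 0.10, adjusted p = 0.184). Endothelial markers were higher in 18 of 20 (median 0.82, camera adjusted p = 1.46e-10; 9 adjusted over the list alone), with Cldn5 at 6.88 ± 1.28 CPM against 2.61 ± 0.393 and Sox17 at 1.25. Decidua and uterus markers were higher in 17 of 21 (median 1.08, adjusted p = 5.72e-07; 2 adjusted over the list alone), with Hand2 at 9.87 ± 5.11 CPM against 2.19 ± 1.53 and a median of 1.900 without control2_placenta_M replicate 2. These lists had adjusted p = 0.362 with an estimated correlation. Over placentas, the decidual collagen-binding gene Dcn ranged from 16.9 to 491.8 CPM. Myeloid markers were higher in 17 of 22 (median 0.95, adjusted p = 1.49e-05; 2 adjusted over the list alone, 0.401 with an estimated correlation), with Adgre1 at 2.74.

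All 43 nuclear oxidative phosphorylation genes were lower in keto males (median -0.23, adjusted p = 8.06e-14; 9 adjusted over the list alone, 0.362 with an estimated correlation), with Ndufa4 at -0.39, and 11 of 12 mitochondrially encoded genes were lower (median -0.63, adjusted p = 2.8e-09; 6 adjusted over the list alone, 0.362 with an estimated correlation), with ND2 at -0.81. Fatty acid oxidation genes were lower in 19 of 23, with Etfb at -0.50 and Hadh at -0.44 (adjusted p = 0.000912, 0.362 with an estimated correlation); their median of -0.176 was -0.091 without control2_placenta_M replicate 2. Ketone body genes were lower in 11 of 12 (median -0.29, adjusted p = 0.00586, 0.362 with an estimated correlation), with the transporter gene Slc16a1 at -0.29 and Oxct1, the enzyme that activates acetoacetate for use, at -0.37, and the median was -0.185 without keto_placenta_M replicate 2. Between the sexes, the effect on the mitochondrially encoded list differed by a median of -1.28 (adjusted p = 5.32e-21, 0.048 with an estimated correlation). No single gene passed for that difference (1410 at an unadjusted p < 0.05; DESeq2 62, limma-voom 0) or for the average of both sexes (1122; DESeq2 29, limma-voom 0).

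Brain was compared between keto and control2 to ask whether the exposure left differences there. Cell cycle genes were lower in keto females and higher in keto males, and hindbrain markers were higher in keto females and lower in keto males, with large differences between brains of one group (camera adjusted p = 3.6e-12 and 1.23e-09 for the difference between the sexes, 0.609 with an estimated correlation). Within a sex these lists had adjusted p = 0.911 in females and 0.521 in males with an estimated correlation. No gene passed in females (edgeR; 224 at an unadjusted p < 0.05; DESeq2 5, limma-voom 0) or in males (556; DESeq2 6, limma-voom 0), among 15420 tested. Pop4 measured 15.5 ± 1.76 CPM against 53.7 ± 15.4 in females (log2 -1.79 ± 0.35, adjusted p = 1), and Wdfy1 measured 17.7 ± 3.63 against 103.9 ± 25.3 in males (-2.55 ± 0.44, adjusted p = 0.789).

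Cell cycle genes were lower in 34 of 35 in keto female brains (median -0.27, camera adjusted p = 6.23e-10; 0.0632 without keto_brain_F replicate 3, 0.911 with an estimated correlation) and higher in 35 of 35 in keto males (median 0.33, adjusted p = 9.9e-08; 0.126 without keto_brain_M replicate 1, 0.521 with an estimated correlation). Without these libraries the medians were -0.102 and 0.062. The female median was also -0.440 and -0.522 without control2_brain_F replicate 3 and keto_brain_F replicate 2, and the male one 0.151 and 0.563 without control2_brain_M replicates 1 and 3. Mki67 gave 237.2 ± 51.7 CPM against 140.4 ± 83.1 in males. Midbrain and hindbrain markers were higher in 37 of 37 in females (median 1.40, adjusted p = 2.53e-08, 0.911 with an estimated correlation) and lower in 31 of 37 in males (median -0.77, adjusted p = 6.1e-06; 0.143 without keto_brain_M replicate 1, 0.521 with an estimated correlation). Hindbrain medians were 2.317 and 0.735 in females without control2_brain_F replicate 3 and keto_brain_F replicate 3, and -0.315 and -1.370 in males without keto_brain_M replicates 1 and 3. With all libraries these medians were unchanged when members with too few counts were held at 3 counts over the group. Hoxb3, a patterning gene of the hindbrain, measured 2.19, 0 and 63.7 CPM in the keto females, 45.0, 47.1 and 0 in the control2 males, at most 5.39 in the keto males and at most 0.0892 in the control2 females. Hoxc4 was high in the same brains: 25.1 CPM in keto_brain_F replicate 3, 24.3 and 15.1 in control2_brain_M replicates 1 and 2, at most 0.156 elsewhere. The share of hindbrain in each sample was not measured, so these lists do not separate that share from an effect of keto.

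**Figure D4:**
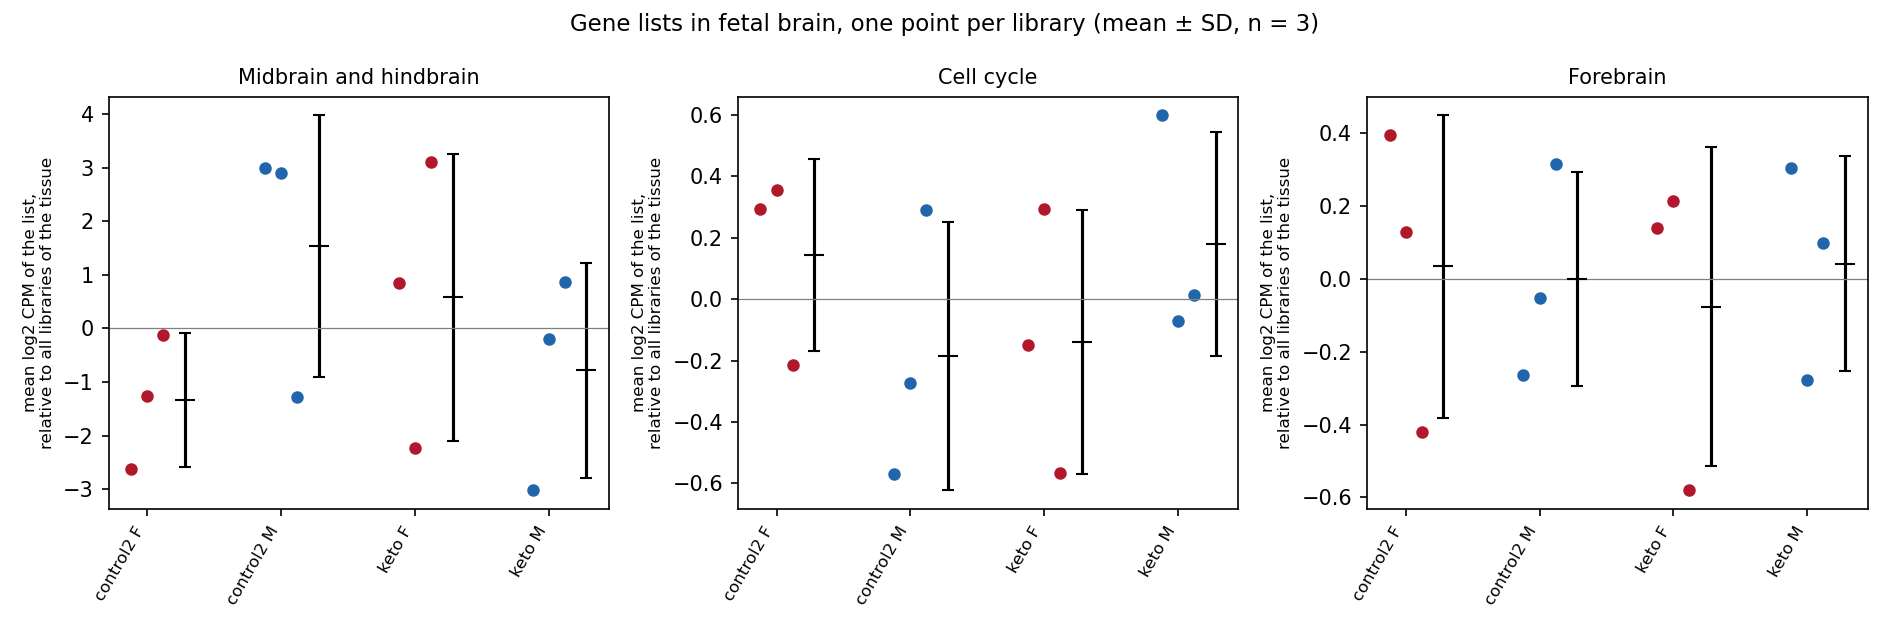
Mean log2 CPM of the hindbrain, cell cycle and forebrain lists relative to all brain libraries (y axis) by group (x axis), 1 point per library with the mean ± SD (n = 3). The hindbrain list scores 2.992, 2.896 and -1.276 in the control2 males and 0.851, -2.221 and 3.103 in the keto females.

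Further lists passed in male keto brains. Nuclear oxidative phosphorylation genes were lower in 41 of 43 (median -0.21, adjusted p = 5.34e-08; 0.109 without control2_brain_M replicate 1), with Cox5a at -0.27, and extracellular matrix genes were lower in 26 of 28 (median -0.39, adjusted p = 9.9e-08), with the collagen gene Col1a1 at -1.13 and a median of -0.242 without keto_brain_M replicate 1. Genes of DNA and histone methylation were higher in 22 of 24 (median 0.19, adjusted p = 4.29e-06), with Tet2 at 0.62, Kmt2a at 0.61 and Tet3 at 0.32. Each of these had adjusted p = 0.521 with an estimated correlation. They moved with control2_brain_M replicate 1, which scored -0.53 for the methylation genes (other control2 males -0.08 and 0.054, keto males 0.009 to 0.147), 0.436 for oxidative phosphorylation (other brains -0.172 to 0.067) and 0.511 for ribosomal proteins (other brains -0.24 to 0.186). It was the only brain library with the third code of RNA extraction and of clean-up, and without it the methylation list had adjusted p = 0.0202 and a median of 0.082, and the oxidative phosphorylation list a median of -0.030. The methylation median was 0.344 without control2_brain_M replicate 3. No gene passed for the difference between the sexes (790 at an unadjusted p < 0.05; DESeq2 8, limma-voom 0) or their average (133; DESeq2 2, limma-voom 0), and adding the RNA clean-up batch left 0 in the brain. Single left-out libraries gave 1 gene in males (keto_brain_M replicate 1 or 2), 1 in the difference (keto_brain_M replicate 1) and 1 or 2 in the average (keto_brain_M replicate 2 or 3).

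The effects of keto and of βOHB alone, which differ by the added AcAc at the same 2 mM βOHB, were compared directly within each sex. Both female liver comparisons had 1240 of the genes called after keto, and 96.6% of these had the same sign after βOHB (median log2 0.33 in the direction of the call). Over all genes the share was 70.5%. Control1 females scored -0.461, -0.320 and 0.138 for the called genes and control2 females -0.430, -0.436 and -0.289. A shared effect was therefore not separated from a difference of the female controls. No gene passed for a difference between the compounds in female livers (edgeR; 577 at an unadjusted p < 0.05; DESeq2 0, limma-voom 0), male livers (286; DESeq2 0, limma-voom 0), female placentas (544; DESeq2 1, limma-voom 0) or male placentas (818; DESeq2 1, limma-voom 0). In female livers the difference, keto minus βOHB, was 0.07 ± 0.45 (SE) for Foxo3, 0.53 ± 0.33 for Ccne2, 0.43 ± 0.46 for Idi1, 1.39 ± 0.71 for Nrip1, 1.44 ± 0.74 for Mia2 and -2.60 ± 0.88 for Pop4 (adjusted p = 0.999 for each). A difference of this size was therefore neither shown nor excluded, and the compounds were also confounded with the experiment and the RNA extraction batch.

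By list, the interferon response genes were lower after keto than after βOHB in 30 of 30 in female livers (median -1.51, camera adjusted p = 6.02e-25; 10 adjusted over the list alone, 0.344 with an estimated correlation), with Stat1 at -1.63 ± 0.39, and in 27 of 30 in male livers (median -0.86, adjusted p = 8.32e-08, 0.855 with an estimated correlation). These medians were -0.659 without bOHB_liver_F replicate 3 and -0.548 without control2_liver_M replicate 3. In female placentas ribosomal proteins were higher after keto in 72 of 74 (median 0.30, adjusted p = 7.64e-18, 0.629 with an estimated correlation), with a median of 0.199 without keto_placenta_F replicate 1. In male placentas oxidative phosphorylation genes were lower after keto in 42 of 43 (median -0.24, adjusted p = 8.5e-12) and decidual markers higher in 20 of 23 (median 1.53, adjusted p = 7.6e-11, 0.392 with an estimated correlation for both).

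Log2 fold changes were also correlated across genes, which are not independent replicates, so no p is given for them. Female and male effects correlated at r = 0.085 for βOHB liver, -0.273 for βOHB placenta, 0.127 for keto liver, 0.108 for keto placenta and -0.629 for brain. Spearman's rho was -0.174, -0.014, 0.176, 0.054 and -0.388 in the same order, opposite in sign to r in βOHB liver, and 39.5%, 51.1%, 57.4%, 51.4% and 35.4% of genes had the same sign. βOHB and keto effects correlated at r = 0.420 in female livers, 0.003 in male livers, 0.344 in female placentas and -0.166 in male placentas. Here rho was 0.513, -0.073, 0.090 and 0.050, opposite in sign to r in male livers and male placentas, and 70.5%, 45.5%, 51.9% and 54% of genes had the same sign. Genes that make, use or carry ketone bodies did not pass singly in any tissue: in keto female livers Hmgcs2, the rate-limiting enzyme of ketone body synthesis, gave log2 -0.22 ± 0.17 (adjusted p = 0.445), Bdh1 -0.11, Oxct1 -0.08 and Slc16a1 0.06.

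**Figure D5:**
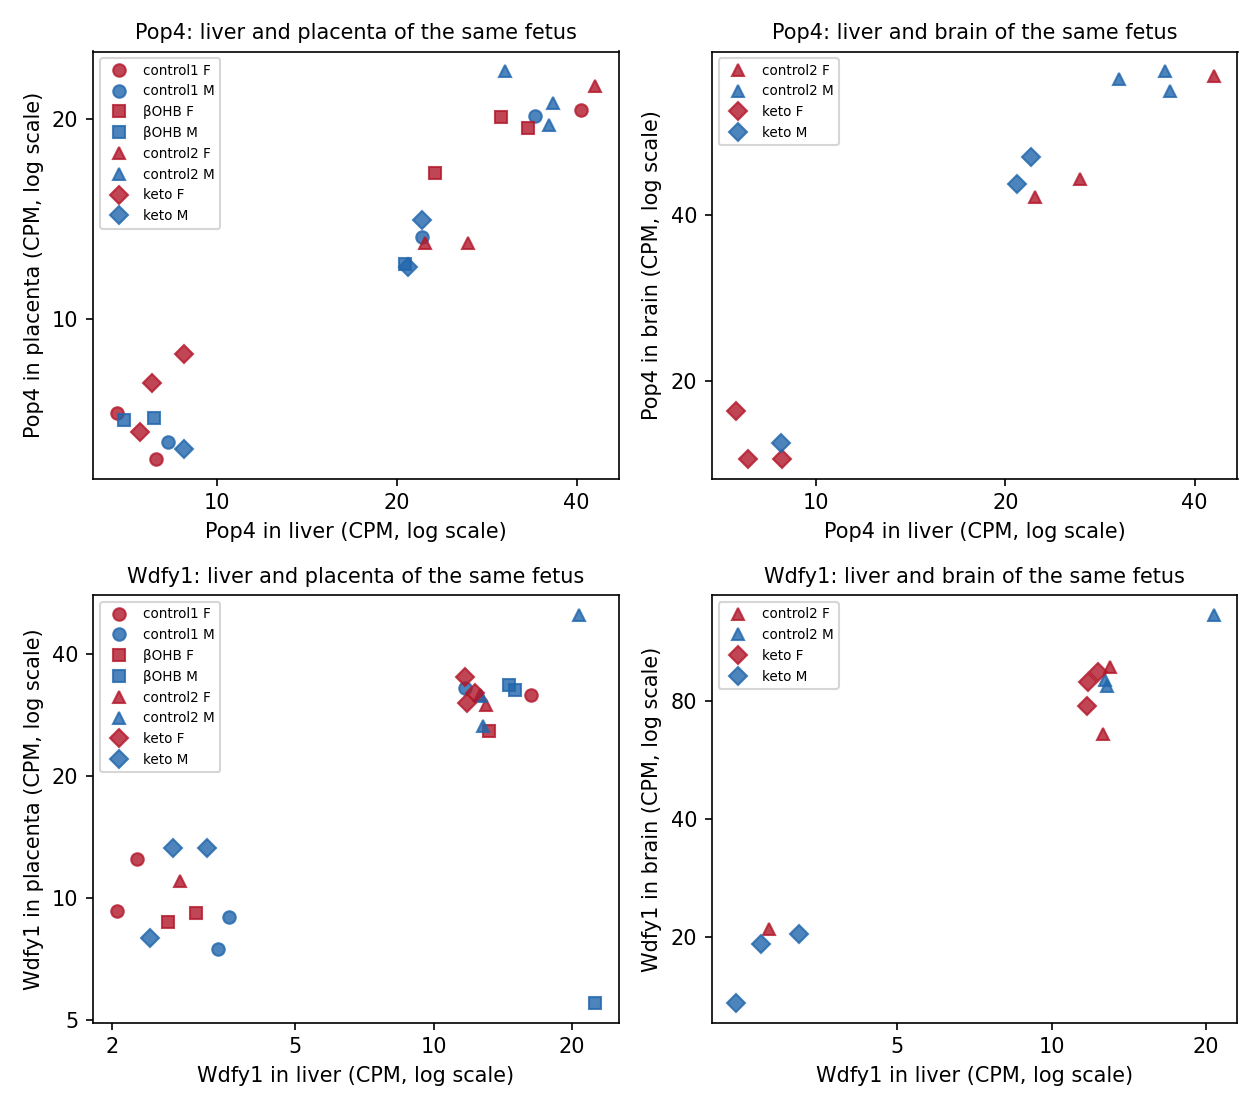
Pop4 and Wdfy1 in liver (x axis, CPM, log scale) against placenta or brain of the same fetus (y axis, CPM, log scale), 1 point per fetus and tissue. Pop4 in liver ranges from 7.44 to 8.81 CPM in keto females and from 22.3 to 42.9 CPM in control2 females.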

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

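In this part, the test of Pop4, the choice of the chromosome 7 interval, the two-sided tests of its genes and all tests on other splits of the libraries were chosen only after the results were seen. The results listed next passed the test of the difference between female and male effects, for lists by camera at the preset correlation. Each value is the male effect minus the female effect in log2. With an estimated correlation every list but the mitochondrially encoded one in keto placenta missed, so these calls do not show effects that depend on sex. The yolk sac list in keto placenta had medians of -1.014 in females and -1.072 in males.

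The gene Cnot6l in keto liver differed by -1.552 (edgeR adjusted p = 0.0326). In βOHB liver the lists that passed, given as list medians, were erythroid (-0.257), fatty acid and triglyceride synthesis (-0.353), interferon response (-0.549), megakaryocyte (0.224), mitochondrially encoded (1.749), nuclear oxidative phosphorylation (0.382), ribosomal proteins (0.617) and skeletal muscle (-2.749), with camera adjusted p from 8.82e-28 to 0.0242 and at least 0.684 with an estimated correlation. In βOHB placenta they were cholesterol synthesis (0.533), decidua and uterus (0.746), erythroid (-0.352), hepatocyte (4.343), immediate early (0.229), interferon response (0.113), labyrinth (-0.312), mitochondrially encoded (-0.417), myeloid (0.744), uterine natural killer cell (1.306) and yolk sac (3.907), with adjusted p from 1.82e-28 to 0.0441 and at least 0.516 with an estimated correlation. The βOHB placenta values include the library labelled bOHB_placenta_M replicate 2.

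In keto liver the lists were DNA and histone methylation (-0.201), megakaryocyte (0.363), nuclear oxidative phosphorylation (0.316) and ribosomal proteins (0.417), with adjusted p from 5.22e-26 to 0.045 and 0.897 with an estimated correlation. In keto placenta they were decidua and uterus (1.458), endothelial (1.027), eye, pigment and pituitary (0.346), immediate early (0.276), imprinted (0.113), junctional zone (-0.355), keratinocyte (-0.244), mitochondrially encoded (-1.282), myeloid (1.499), nuclear oxidative phosphorylation (-0.371), ribosomal proteins (-0.435), trophoblast giant cells (-0.576), uterine natural killer cell (1.018) and yolk sac (0.159), with adjusted p from 1.64e-27 to 0.047. With an estimated correlation the mitochondrially encoded list had adjusted p = 0.048 and the others at least 0.238. In keto brain they were cell cycle (0.611), decidua and uterus (-0.371), DNA and histone methylation (0.240), forebrain (0.406), hepatocyte (-0.796), histone deacetylases and acetyltransferases (0.152), imprinted (-0.264), midbrain and hindbrain (-2.026), neural progenitor (0.247), nuclear oxidative phosphorylation (-0.239), skeletal muscle (0.463) and extracellular matrix (-0.517), with adjusted p from 3.6e-12 to 0.0348 and at least 0.609 with an estimated correlation.

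The 1242 calls in keto female livers followed transcript length: genes higher after keto had a median length of 2040 nt and genes lower 764 nt, against 1432 nt over all genes. After correction for length and GC content, 68.8% of the calls passed again and their median fold change moved from 0.488 to 0.431, which argues against that trend as the whole cause. Over the fits without 1 library the lowest median was 0.439, but calling the genes on all 6 libraries partly builds this in. Of the 1242 calls, 211 still passed without control2_liver_F replicate 1, 366 without control2_liver_F replicate 2 and 393 without keto_liver_F replicate 1. The median therefore does not decide how far single libraries set the calls. The control2 females were outermost of the 4 groups in 99.1% of the called genes and the keto females in 60.6%, positions partly built in by calling on this contrast, and a difference of these controls from the other livers stays open beside an effect of keto. Among the 10 splits of the 6 libraries, 1 gave as many calls, the real one, and the highest other count was 1; 10 splits are too few for a share under 0.05.

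Decidual markers in male keto placentas could come from more maternal tissue in the sample. Maternal cells carry Xist, and over the 11 male-labelled placentas with Y-linked reads the decidual score followed Xist with r = 0.601 (permutation p = 0.0816) and rho = 0.711 (permutation p = 0.0171), the only relation of this kind tested. Without the 2 libraries farthest from the median of Xist, r was 0.924, and within the 6 libraries of the keto experiment it was 0.710; the βOHB experiment had 5, too few for a value. The test left open whether dissection or the treatment set the share of decidua.

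Pop4, low in keto female liver and brain, may differ between fetuses by an inherited allele, since the labels name embryos of a cross between strains. Its level in liver followed that in placenta of the same fetus with r = 0.963 (permutation p = 0.0005, 23 fetuses, deviations from group means). Such a difference would fall on groups of 3 fetuses by chance, so an effect of keto on Pop4 cannot be separated from the draw of fetuses. Of 8 named genes on chromosome 7 between 44 and 47 Mb, the 4 measurable in both tissues had a median r of -0.437 (one-sided permutation p = 0.984). By the limit set before this test, that counts against an allele acting alike in both tissues. Over 61 genes of the interval the median r was 0.058, against 0.108 over all genes, and 0 were above 0.8. However, Hsd17b14 at -0.761 and Ap2a1 at -0.732 followed the fetus in opposite directions in the tissues (two-sided permutation p = 0.0077 and 0.0096, adjusted over these 4 genes 0.0192 for both). Pold1 gave -0.056 and Bcat2 -0.141. An allele acting oppositely in the tissues therefore stays open for Hsd17b14 and Ap2a1.

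Other splits of the same libraries were counted for each contrast. For the average of both sexes in keto liver, 2 of 81 splits gave at least the real 246 calls, with the real one counted. The highest other count was 467, so another split gave more calls than the real one. The split tests were chosen after the results were seen, and the share was not adjusted over the contrasts counted. The share therefore does not exclude chance. For the sex difference in keto liver, 22 of 81 splits gave at least the real 1 (highest other 2335). Chance cannot be excluded there either. For the contrasts over 81 splits with a real count of 0, all 81 gave as many, as any split must, so the share carries no information. The highest other counts were 9 and 118 for the sex difference and average in βOHB liver, 506 and 503 in βOHB placenta, 8 and 8 in keto placenta, 2 and 2 in brain, and 3070, 0, 123 and 0 for keto minus βOHB in female livers, male livers, female placentas and male placentas. For the contrasts over 81 splits, libraries were drawn separately in each sex and experiment. A split could therefore keep or swap the real grouping of a single sex. High counts such as 2335 against 1 and 3070 against 0 thus do not separate a structure of the samples from the real female difference. For the within-sex contrasts with a real count of 0, all 10 splits likewise gave as many, which the count of 0 fixes in advance. The highest other counts were 480 and 1 in βOHB liver females and males, 651 and 2 in βOHB placenta, 2 in keto liver males, 0 and 1 in keto placenta and 35 and 2 in brain.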

How the results depend on the processing

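In this part, the fits of all 60 libraries, the batch terms, the length and GC correction and the list tests with libraries left out were chosen only after the results were seen. Of 910 pairs of a named gene and a contrast, 51 were called, and these kept the sign of their log2 fold change under every alternative run on them. All 51 also passed with DESeq2 and with RLE factors, 49 with limma-voom, 46 without a filter, 41 after length and GC correction, 27 in the edgeR fit of all 60 libraries and 19 with the replicate block, while with 1 library left out 285 of their tests passed and 117 did not. Of the pairs not called, 95 passed with DESeq2 and 52 in the edgeR fit of all 60 libraries. The 1242 calls of keto female liver stayed within 1.5-fold with DESeq2 (1850), limma-voom (1096), RLE factors (1253), no filter (1164) and length and GC correction (1056). The cause of the changes given next was not tested.

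DESeq2 called 16, 1 and 3 genes in βOHB liver females, males and average, 65 and 7 in βOHB placenta females and average, 4, 253 and 900 in keto liver males, sex difference and average, 4, 236, 62 and 29 in keto placenta females, males, difference and average, 5, 6, 8 and 2 in the same brain contrasts, and 1 each for keto minus βOHB in female and male placentas. For the sex difference in keto liver, limma-voom called 0 and the fit without a low-count filter 19. With only the 6 libraries compared there were 2 genes in keto liver males, 1 and 2 in keto placenta females and males and 2 in brain males, and with only the 12 libraries of that sex 1 for keto minus βOHB in male placentas. In one edgeR fit of all 60 libraries there were 163, 1 and 23 in βOHB liver females, difference and average, 149, 3 and 1 in βOHB placenta, 525, 0 and 81 in keto liver, 85, 7 and 2 in keto placenta males, difference and average, 9, 10 and 23 in brain females, males and difference, and 2 for keto minus βOHB in female livers.

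With limma-voom on all 60 libraries there were 141 in βOHB liver females, 100 in βOHB placenta females, 442 in keto liver females, 1 and 3 in keto placenta females and males and 1 in brain males. Adding batch terms with approximate standard errors gave 306 and 3 in βOHB liver females and males, 79 in βOHB placenta females, 40 in keto liver males, 157 and 623 in keto placenta females and males and 2 and 1 in brain; with exact standard errors these were 176 and 0, 61, 0, 1 and 3, and 2 and 2, and keto liver females had 539.

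With the replicate number as a block there were 314 calls in keto liver females, 0 for the sex difference and 0 for the average, 1, 1, 1 and 3 in keto placenta females, males, difference and average, and 1 for keto minus βOHB in male placentas; the block changed no other call count, and among the lists of female keto placentas no call other than those of fatty acid oxidation, ketone body and choroid plexus genes. Outside female keto placentas, where all 6 libraries correlated best with their own number, the numbers met no pairing rule: r was -0.16, -0.08 and -0.15 in βOHB liver females and -0.07, -0.05 and 0.08 in males, -0.52, -0.04 and -0.45 and -0.17, 0.09 and 0.25 in βOHB placenta, -0.03, 0.01 and 0.00 and -0.15, -0.02 and 0.01 in keto liver, 0.48, 0.40 and -0.03 in keto placenta males, and 0.08, 0.20 and 0.42 and -0.24, 0.17 and -0.44 in brain.

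With single libraries left out, calls ranged from 0 to 1480 in βOHB liver females (1480 without control1_liver_F replicate 3, 1 without bOHB_liver_F replicate 1), 0 to 441 for its sex difference and 0 to 13 for its average (the highest without control1_liver_F replicate 3), and 0 to 64 in βOHB placenta females (without control1_placenta_F replicate 3). In keto liver they ranged from 213 (without control2_liver_F replicate 1) to 1268 in females, with 378 without control2_liver_F replicate 2 and 416 without keto_liver_F replicate 1; from 0 to 2 in males (2 without keto_liver_M replicate 2, 1 without replicate 1); from 0 to 174 for the sex difference (174 without control2_liver_F replicate 3, 2 without control2_liver_F replicate 2, control2_liver_M replicate 2 or keto_liver_F replicate 1); and from 12 (without keto_liver_M replicate 3) to 1123 for the average. In keto placenta they ranged from 0 to 1 in males, difference and average, and in brain from 0 to 1 in males and difference and 0 to 2 in the average.

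Of 109 lists called within a sex, 10 had a median whose sign turned with 1 library left out, and in 83 more it moved by over 1.5 times. With an estimated correlation 0 lists passed in 23 of the 24 contrasts and 1 in the sex difference of keto placenta. With single libraries left out, the lists passing ranged from 6 to 12 in βOHB liver females (5 with all libraries), 5 to 10 for its sex difference (8), 10 to 16 for the βOHB placenta average (16), 5 to 10 in keto liver females (6), 2 to 9 in males (5), 4 to 12 for the difference (4) and 4 to 9 for the average (5), 9 to 19 in keto placenta females (15) and 14 to 22 in males (14), and 4 to 11 in brain females (8), 9 to 18 in males (19) and 11 to 19 for the average (12).

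Correlations of female with male effects over genes of at least 10 CPM were -0.320 in βOHB liver and 0.225 in keto liver, and of βOHB with keto effects 0.673 in female and -0.074 in male livers. With single libraries left out, female and male effects correlated from -0.277 (without control1_liver_F replicate 2; also -0.097 without control1_liver_M replicate 2) to 0.415 in βOHB liver, -0.425 to -0.029 in βOHB placenta, 0.011 to 0.269 in keto liver, -0.118 (without control2_placenta_M replicate 2; also -0.042 without control2_placenta_F replicate 3) to 0.190 in keto placenta and -0.676 to -0.195 in brain (without keto_brain_F replicate 3). Effects of βOHB and keto correlated from 0.216 to 0.511 in female livers, 0.191 to 0.516 in female placentas and -0.245 to 0.072 in male placentas (0.072 without control2_placenta_M replicate 2). In male livers they ranged from -0.131 to 0.072, with -0.131 without control2_liver_M replicate 1, -0.052 without keto_liver_M replicate 1, -0.030 without control1_liver_M replicate 3, -0.027 without bOHB_liver_M replicate 1 and -0.024 without bOHB_liver_M replicate 2.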

Other observations

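In this part, the tests on genes followed across tissues of one fetus and the comparison with the deposited tables were chosen only after the results were seen. Cell-type markers other than those described in the report moved in several tissues. In male βOHB livers the myeloid markers were higher in 26 of 28 (median 0.131, camera adjusted p = 9.75e-05; 0.925 without control1_liver_M replicate 1; 0.603 with an estimated correlation). Extracellular matrix genes were higher in 22 of 26 in male keto livers (median 0.132, adjusted p = 0.00288; 0.366 without keto_liver_M replicate 2; 0.983 with an estimated correlation), with Vim at 0.23 and Sparc at 0.24. In female keto brains the forebrain list was lower in 14 of 18 (adjusted p = 0.0202; 0.955 without keto_brain_F replicate 3; 0.911 with an estimated correlation), with Neurod6 at -0.52, Fezf2 at -0.59 and Tbr1 at -0.47. Lists with a smallest adjusted p of 0.122, 0.126 and 0.195 over the within-sex contrasts were choroid plexus, eye, pigment and pituitary, and inhibitory neuron.

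Some genes kept a fetus's level across its tissues. Over 23 fetuses, Wdfy1 in liver followed Wdfy1 in placenta with r = 0.841 (permutation p = 0.0003), and over the 12 fetuses with brain r was 0.962 between liver and brain; for Pop4 it was 0.927. Of 11412 genes, 110 had r above 0.8 between liver and placenta, against a median of 1 and at most 40 when fetuses were reassigned within groups in 1000 permutations; 16 of the 110 were annotated pseudogenes. For each placenta, the 116 to 135 genes with r above 0.8 over the fetuses other than its own (and other than that of the library labelled bOHB_placenta_M replicate 2) were correlated with each liver. The library labelled bOHB_placenta_M replicate 2 had r = 0.315 with the liver of its own fetus code and at most 0.159 with any other liver, and the other placentas had 0.329 to 0.851 with their own. Of the 24 placentas, 23 correlated best with their own liver, and keto_placenta_F replicate 1 did not (r = 0.329 with its own and 0.381 with another). Wdfy1 was 5.5 CPM in the library labelled bOHB_placenta_M replicate 2, against 22.4 CPM in the liver of its fetus code.

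Mitochondrially encoded genes took 1.34% to 6.18% of the counts of liver libraries, 0.52% to 1.42% in placenta and 0.82% to 1.69% in brain. The haemoglobin genes that were summed, which did not include Hbb-b1, took 4.10% to 7.44%, 0.17% to 0.92% and 0.08% to 0.21%. Albumin ranged from 0.0467 to 410.1 CPM and Apoa1 from 0.654 to 2246.7 CPM over the placentas.

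The genes in the authors' deposited tables are those that a limit of 0.5 CPM in at least 3 libraries gives. At an adjusted p under 0.05 the authors' deposited tables call 307 and 3 genes in βOHB liver females and males, 79 and 0 in βOHB placenta, 1124 and 41 in keto liver, 157 and 621 in keto placenta and 3 and 1 in brain. A limma-voom fit of all 60 libraries with the batch codes as terms and approximate standard errors gave t values with r = 1.0000 across genes to those in the authors' deposited tables, genes not being independent replicates. In keto female livers, 737 of the 1124 genes called in the authors' deposited table were also called by edgeR, all with the same sign, and 486 with exact standard errors. The approximate error over the exact one had a 1st percentile down to 0.441 and a 99th up to 4.523 over contrasts.

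The correlation of βOHB with keto effects across genes was set against 200 splits of the libraries. In female livers the split fits gave r = 0.445 for the real labels, reached by 2 of 200 splits with the real one counted (permutation p = 0.01). Another split therefore gave an r at least as high, so the real labels were not shown to be the most extreme. In female placentas r was 0.390, reached by 14 of 200 splits, in male livers -0.014 (118 of 200) and in male placentas -0.114 (145 of 200).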
